A study of Mus musculus with 10 samples.

How the data were processed

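Gene expression was measured on 10 Affymetrix arrays, hybridised with biotin-labelled cDNA that was made from total RNA of immortalized mouse macrophages. The labels name a wild-type B6 line and a line without Toll-like receptor 9 (TLR9). Each line was left unstimulated or was given β-1,3 glucan beads, particles made of the fungal cell wall sugar that the receptor Dectin-1 binds, at 20 beads per cell for 4 h. Per the labels, 100 ng of total RNA went into the amplification and 5.5 µg of cDNA was labelled.

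The deposited table holds log2 signal values per probe set, made by the authors with RMA per the submitters' processing notes. RMA corrects the probe signals for background, brings the probe distributions of the arrays it is run on to a common shape, and summarises the probes of each probe set. Its version, the software, the probe annotation and any filter are not given in the sources used here. The values ran from about 3 to about 14, as log2 values do. The median over all probe sets was 5.93, 5.75 and 5.90 in the unstimulated wild-type arrays, 5.78, 5.76 and 6.10 in the wild-type bead arrays, 5.86 and 5.95 in the unstimulated knockout arrays, and 5.97 and 5.84 in the knockout bead arrays. The arrays were thus not centred on a common median. The scale (log2) follows from the values. Whether the 10 arrays were normalised together, and on what they were centred, stays unknown.

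The table held 28853 probe sets. Of these, 21789 carried 1 gene symbol in the platform annotation, 1621 carried several and 5443 were not named. Current symbols were matched by Entrez ID for 21698 of the single-gene probe sets. The genes tested numbered 19938, each represented by its probe set with the highest mean over the 10 arrays, and 999 genes had more than 1 probe set. Probe sets shared by several genes or not named were left out of the gene tests and were tested separately. No gene was removed for low signal.

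The 10 arrays were assigned to their groups by the labels alone, with 3 arrays for each wild-type group and 2 arrays for each knockout group. A linear model with 4 group means was fitted to the deposited log2 values with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without trend and not robust), with 6 residual and 3.23 prior degrees of freedom. The 5 contrasts were the bead response of each line, the difference between the bead responses, and the difference between the lines without and with beads. Tests were two-sided, and genes passed at a Benjamini-Hochberg adjusted p under 0.05 over the 19938 genes. Differences are on the log2 scale with the standard error (SE) of the fit. The labels do not state that the arrays of a group came from separate cultures, so the p-values measure only the spread between these arrays. The small number of arrays limits the precision. No paired analysis was possible because the labels give no replicate numbers that the groups share. The titles carry bracketed array numbers whose meaning is not described, and all knockout arrays have lower numbers than the wild-type arrays. If these numbers follow an order of handling, which is not stated, that order cannot be told apart from the line.

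Gene lists were compared with all other genes by camera in limma, with a preset correlation between genes of 0.01 and, beside it, with an estimated correlation. The p-values were adjusted over the 23 lists of a contrast. The fry test was run too. It asks whether the genes of a list move, on balance, in 1 direction (or, in its mixed form, in either direction) and does not compare them with other genes. The lists covered cytokines, chemokines, NF-kappaB regulators, immediate early genes, interferon-stimulated genes, Dectin-1 and other C-type lectin signalling, Toll-like receptors with their adaptors and trafficking factors, eicosanoid synthesis, oxidative burst, NRF2 antioxidant genes, lysosome genes, cholesterol biosynthesis and efflux, glycolysis and hypoxia, the cell cycle, matrix remodelling with adhesion and coagulation, MHC class I and class II presentation, macrophage identity, sex-linked transcripts, and markers of dendritic cells, granulocytes, lymphocytes and fibroblasts or stroma. They held 540 entries, of which 496 were measured, 12 lay only on probe sets shared by several genes and 32 had no named probe set and were not analysed here.

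The contrasts, the tests, the lists, the alternatives planned and the rule for naming genes were chosen before the data were examined. The rule took, per contrast, up to 12 genes with the highest and 12 with the lowest log2 difference among those that passed and whose arrays did not overlap between the groups, leaving out predicted genes and small RNAs. It also took up to 4 members per list with the largest change in size, among those that passed or, where none passed, among all, and Tlr9, Clec7a and Tnf in each contrast.

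The alternatives planned were a trended or robust eBayes, centring on the median or the 75th percentile, quantile normalisation of the table, filters on mean signal (above 5, which kept 14505 genes, or above the median, which kept 9969), the mean over a gene's probe sets, array weights, fits of the compared groups alone, a minimum change of 1 on the log2 scale, and leaving out each array in turn. Added after seeing the data were a covariate (the SD over genes of each array's values, called the signal range below), list tests with each array left out in turn, and list tests under each of the 3 scalings. Background correction and probe summary were not changed, since no scanner files were used here.

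The fit was tested on simulated data with 200 changed genes among 19938 in this design. With true changes of 0.5, 1, 2 and 3 on the log2 scale (50 genes each), 28%, 76%, 94% and 100% were recovered for the wild-type bead response, with 10 false calls. For the knockout bead response 20%, 64%, 100% and 100% were recovered with 6 false calls. The difference between the responses gave 0%, 54%, 86% and 98%, with 3 false calls. Between the lines, 14%, 60%, 98% and 100% were recovered without beads (4 false calls) and 20%, 72%, 94% and 100% with beads (13 false calls). A simulated list of 30 genes shifted by 0.5 gave a camera p of 6.1e-46, and 2 of 100 unshifted lists had a p under 0.05. The simulated values were drawn independently for each gene and array, without correlation between genes and without an array that stands apart. The simulation therefore does not test the preset correlation of camera, and its recovery may not hold for the real arrays.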

Results

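The series asked which genes differ in expression when wild-type and TLR9 knockout macrophages meet β-1,3 glucan beads. It held 3 unstimulated and 3 bead-stimulated wild-type arrays, and 2 unstimulated and 2 bead-stimulated knockout arrays, with beads given for 4 h. TLR9 is an endosomal receptor for DNA rich in unmethylated CpG. Each genotype was represented by a single named line, so differences between the lines and effects of the genotype cannot be told apart here.

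The arrays fell apart mainly by line. Within the lines they did not group by beads throughout. Each knockout array correlated best with a knockout array of the other treatment (Pearson r across genes 0.997, against 0.994 and 0.995 within the groups). Wild-type bead array 3 and unstimulated array 2 also correlated best with a wild-type array of the other treatment (0.986 and 0.996). Wild-type bead arrays 1 and 2 paired with each other, as did unstimulated arrays 1 and 3 (0.998 each). The first principal component held 56.8% of the variance between arrays and parted the 4 knockout arrays from the 6 wild-type arrays. The second held 29.8% and set wild-type bead array 3 apart, at a score of 49.6 against at most 7.35 in any other array. That array correlated with its group mates at a mean Pearson r of 0.973 across genes, while the other 9 arrays reached 0.985 to 0.997. Its SD over genes was the smallest of the 10, at 1.75 against 1.86 to 2.00, and its median was the highest. Against arrays 1 and 2 of its group, genes of low signal (under 5) read higher by a median of 0.23 and genes between 9 and 11 read lower, with a median of -0.42.

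**Figure D1:**
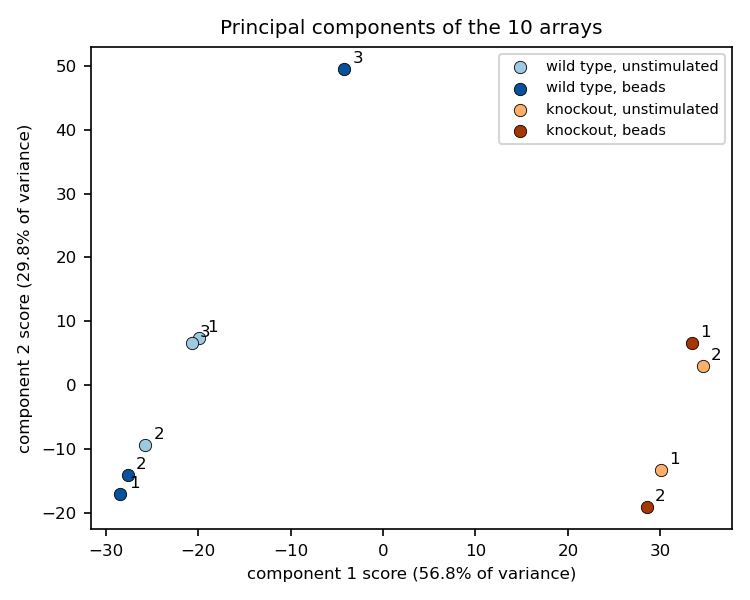
Scores of the 10 arrays on the first (x axis) and second (y axis) principal components of the log2 values over 19938 genes, with the share of variance on each axis; points are arrays, coloured by group and numbered by replicate. The lines separate along the first component and wild-type bead array 3 stands at 49.6 on the second.

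Tlr9 itself was read by probe set 10588479. Its log2 signal was 7.32, 6.91 and 7.25 in the unstimulated wild-type arrays and 7.44 and 7.62 in the unstimulated knockout arrays, a difference of 0.37 ± 0.15 (SE) that did not pass (adjusted p = 0.244). With beads it was 7.03, 7.21 and 7.44 in wild type and 7.35 and 7.31 in knockout (0.10 ± 0.15). The difference without beads was 0.24 without unstimulated wild-type array 2, and that with beads ran from 1.04e-04 to 0.21 without wild-type bead array 1 or 3. Where this probe set lies relative to the deleted part of the gene is not given in the sources used here, so these values do not bear on whether the labels of the lines are right.

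Without beads, the knockout line expressed far more of the genes that interferon induces than the wild-type line. Irf7, the transcription factor that amplifies type I interferon production, was 34.8-fold higher (log2 5.12 ± 0.13, SE), with 2 knockout and 3 wild-type arrays. Oasl2 was 26.8-fold higher (4.74 ± 0.11) and the chemokine Cxcl10 17.6-fold (4.14 ± 0.18). Rtp4 differed by 5.25 ± 0.17, but its wild-type signal lay below the 25th percentile of all 3 arrays, without detection calls, so the size of its difference is not a measured fold. In the other direction Ccn3, a secreted matricellular protein, differed by -6.28 ± 0.11 on the log2 scale, followed by the glutathione transferase Gstp1 (-5.10 ± 0.16), Eya1 (-4.93 ± 0.16) and the ubiquitin ligase Nedd4 (-4.85 ± 0.10). The protease Ctsk (-4.60 ± 0.15), the lipid carrier Apoe (-3.58 ± 0.16) and the mannose receptor Mrc1 (-3.50 ± 0.20) were lower too. The limma test passed 1645 of 19938 genes (8.25%), 755 higher and 890 lower in the knockout line, of which 307 and 198 differed at least 2-fold. The smallest adjusted p was 1.1e-08, for Ccn3.

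Further genes among the 12 highest were the calcium-binding S100a6 (4.23 ± 0.17), the transporter Slc43a3 (3.98 ± 0.21) and the prostaglandin-degrading enzyme Hpgd (3.93 ± 0.18). They also held the lectins Clec2d (3.61 ± 0.19) and Clec12a (3.46 ± 0.24), Ifi209 (3.52 ± 0.20), Ifi27l2a (3.49 ± 0.21) and the chemokine Cxcl16 (3.39 ± 0.24). The 12 lowest also held Klk1b11 (-3.44 ± 0.14), Tspan10 (-3.40 ± 0.17), Il13ra1, a chain of the interleukin 13 receptor (-3.33 ± 0.24), Arsg (-3.20 ± 0.15) and the calcium pump Atp2a3 (-3.07 ± 0.18). Ifi209 in wild type and Klk1b11 in knockout also lay below the 25th percentile of each array of the group.

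**Figure D2:**
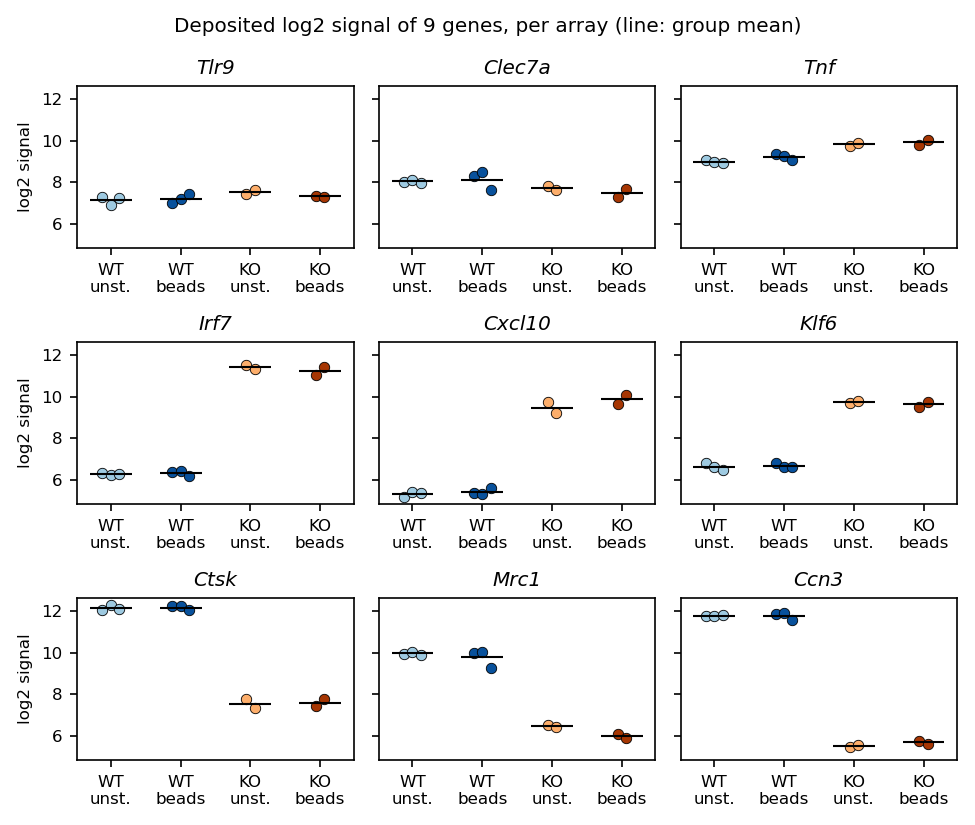
Deposited log2 signal (y axis) of 9 genes in each array, by group on the x axis; points are single arrays and the line is the group mean. Irf7, Cxcl10 and Klf6 lie higher and Ctsk, Mrc1 and Ccn3 lower in the knockout arrays with and without beads, and the Tlr9 arrays of the lines overlap with beads.

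Of 35 measured interferon-stimulated genes, 30 were higher in the unstimulated knockout line and none was lower (32 and 0 adjusted over the list alone), with a median of 2.26. Ifnb1, Mx1, Gbp5, Zbp1 and Herc6 did not pass. The camera test gave an adjusted p of 1.7e-57, and 0.00371 with an estimated correlation. MHC class I presentation, which interferon also induces, was higher too, in 7 of 14 genes (9 adjusted over the list alone; camera adjusted p = 5.4e-09). Among them were H2-Q4 (1.34 ± 0.16), the peptide transporter subunit Tap1 (1.33 ± 0.12), Tapbp (1.25 ± 0.14) and the immunoproteasome subunit Psmb9 (0.95 ± 0.13). NF-kappaB subunits and feedback regulators were higher in 11 of 23 (13 adjusted over the list alone; camera adjusted p = 8.1e-15). Tnip3 (3.11 ± 0.31), Nfkbie (1.62 ± 0.12), Birc3 (1.46 ± 0.14) and Otud1 (1.13 ± 0.11) led them. Immediate early genes were higher in 13 and lower in 1 of 32 (19 and 1 adjusted over the list alone; camera adjusted p = 2.0e-14). Klf6 (3.12 ± 0.13), Fos (2.35 ± 0.15), Zfp36 (2.28 ± 0.31) and the phosphatase Dusp1 (2.21 ± 0.15) led. These 4 lists, and no others, also passed with an estimated correlation in both comparisons of the lines; no list did in any bead comparison.

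Cell cycle genes were lower in 14 of 31 and higher in none (24 and 0 adjusted over the list alone), and all 31 had negative values (median -0.69). Mcm2 (-1.30 ± 0.09) and Mcm7 (-1.05 ± 0.13), subunits of the replicative helicase, Ccne1 (-1.29 ± 0.13) and the mitotic kinase Bub1 (-1.02 ± 0.16) had the largest differences among those that passed. Camera gave an adjusted p of 4.2e-19 for this list, and adjusted p = 0.261 with an estimated correlation. Glycolysis and hypoxia genes were lower in 4 and higher in 1 of 22 (6 and 1 adjusted over the list alone; camera adjusted p = 0.00551, but adjusted p = 0.289 with an estimated correlation). The lactate exporter Slc16a3 was at 2.31 ± 0.17, against Ak4 (-0.96 ± 0.24), Pfkfb3 (-0.66 ± 0.13) and Hk2 (-0.58 ± 0.11).

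Toll-like receptors and their adaptors were higher in 9 and lower in 2 of 33 (10 and 2 adjusted over the list alone; camera adjusted p = 3.4e-04, but adjusted p = 0.545 with an estimated correlation). The lipopolysaccharide co-receptor Cd14 (2.46 ± 0.18), Ctss (1.68 ± 0.12) and Tlr2 (1.46 ± 0.12) were higher. Chemokines were higher in 7 and lower in 4 of 25 (7 and 4 adjusted over the list alone; camera adjusted p = 0.0483). That call ended with an estimated correlation (adjusted p = 0.289 with an estimated correlation) and without any of 4 arrays, wild-type bead array 1 or 3, unstimulated wild-type array 2 or unstimulated knockout array 1 (adjusted p = 0.0546 to 0.0973). Beside Cxcl10 and Cxcl16, Ccl5 (3.16 ± 0.23) and Cxcl14 (2.12 ± 0.14) were higher.

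The other lists did not pass camera, though single members did. Macrophage identity markers went both ways, 8 higher and 5 lower of 25 (9 and 6 adjusted over the list alone). The monocyte marker Cd14 was higher, and Apoe, Mrc1 and the transcription factor Maf (-2.29 ± 0.14) were lower; their median was 0.17 and their mean -0.01. In the Dectin-1 and C-type lectin list 4 were higher and 2 lower of 29 (5 and 3 adjusted over the list alone). Src (1.63 ± 0.18) and Clec4a2 (1.01 ± 0.13) were higher, and Mrc1 and Clec4n (-1.37 ± 0.27) lower. Clec7a, which encodes the β-glucan receptor Dectin-1, differed by -0.30 ± 0.23 and did not pass (adjusted p = 0.71). Cytokines were higher in 4 and lower in 3 of 24 (4 and 3 adjusted over the list alone). Ebi3 (1.97 ± 0.23), Il18 (1.20 ± 0.20) and Tnf (0.83 ± 0.12, adjusted p = 0.00302) were higher and Csf1 (-1.23 ± 0.15) was lower. Of the oxidative burst genes 2 were higher and 1 lower of 15 (2 and 1 adjusted over the list alone). They were the NADPH oxidase subunit Cybb (3.11 ± 0.33), Acod1 (0.64 ± 0.13) and Arg1 (-1.10 ± 0.19); the median was -0.02 and the mean 0.17.

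NRF2 antioxidant genes were lower in 4 and higher in none of 20 (4 and 4 adjusted over the list alone), namely Hmox1 (-1.22 ± 0.10), Slc7a11 (-1.06 ± 0.26), Gclc (-0.75 ± 0.13) and Gsr (-0.52 ± 0.12). Eicosanoid genes were higher in 3 and lower in 2 of 19 (3 and 3 adjusted over the list alone). Hpgd, Ptger4 (1.02 ± 0.13) and Cysltr1 (0.82 ± 0.18) were higher and Ltc4s (-1.58 ± 0.27) lower. Lysosome genes were higher in 3 and lower in 4 of 27 (3 and 7 adjusted over the list alone), with the proton pump subunit Atp6v0d2 at -1.21 ± 0.17 and Npc2 at 0.71 ± 0.15. Cholesterol genes were higher in 2 and lower in 1 of 21 (2 and 2 adjusted over the list alone). They were the exporters Abca1 (1.11 ± 0.16) and Abcg1 (0.77 ± 0.11) and the synthesis enzyme Dhcr7 (-0.83 ± 0.15). Matrix and adhesion genes were higher in 4 and lower in 3 of 25 (5 and 3 adjusted over the list alone). The integrins Itga5 (1.05 ± 0.18) and Itgav (0.97 ± 0.12) were higher, Timp2 (-1.51 ± 0.20) and F7 (-0.88 ± 0.11) lower. MHC class II presentation had 1 of 11 higher (2 higher and 1 lower adjusted over the list alone), Cd74 at 2.05 ± 0.26.

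Markers of other cell types were mostly flat. Bst2 (1.29 ± 0.22), which interferon also induces, was the 1 dendritic cell marker of 13 that was higher (2 adjusted over the list alone), and Il7r (2.99 ± 0.13), below the 25th percentile of all 3 wild-type arrays, the 1 lymphocyte marker of 17 (1 adjusted over the list alone). The median, mean and test had the same sign in every list that passed camera, in each of the 5 comparisons; among the others without beads, the NRF2 and sex-linked lists differed in sign besides the oxidative burst and macrophage lists. None of 16 granulocyte markers, 13 fibroblast and stromal markers or 6 sex-linked transcripts passed in limma, over all genes or adjusted over the list alone.

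The count of 1645 moved by over 1.5 times with several arrays. It was 681 and 733 without unstimulated knockout array 1 or 2, 1048 and 988 without unstimulated wild-type array 1 or 3, and 3668 without wild-type bead array 3, which is not part of the comparison but adds to the spread. It was also 756 after centring on the median, 2483 after quantile normalisation of the table, 3262 in a fit of the compared groups alone, 4451 with array weights and 4297 with each array's signal range as a covariate.

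Of 79 genes named for this comparison that passed, 18 lost their call under at least 1 alternative, all of them after centring on the median or with an unstimulated array left out. They were Acod1, Ak4, Arg1, Bst2, Bub1, Clec4n, Cysltr1, Dhcr7, Gclc, Gsr, Hk2, Il18, Itga5, Ltc4s, Npc2, Pfkfb3, Slc7a11 and Tnf. Of those that did not pass, Mx1, Gbp5 and Herc6 did with array weights and with the covariate.

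**Figure D3:**
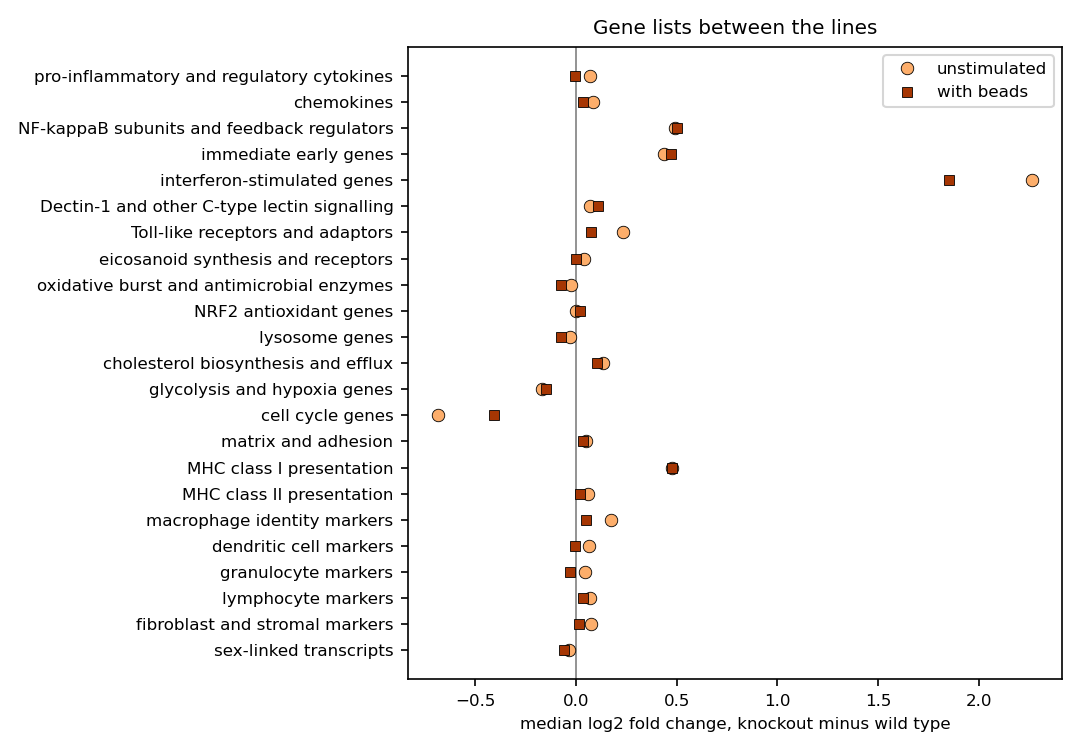
Median log2 difference, knockout minus wild type (x axis), of the measured members of each of the 23 gene lists (y axis), without beads (circles) and with beads (squares). Interferon-stimulated genes lie at 2.26 and 1.85 and cell cycle genes at -0.69 and -0.41.

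With beads, the lines differed largely in the same genes, since 1190 genes passed both with and without beads. Irf7 was higher in the knockout line by 4.91 ± 0.13 on the log2 scale, Rtp4 by 4.68 ± 0.17, Cxcl10 21.8-fold (4.44 ± 0.18), S100a6 21.5-fold (4.43 ± 0.17) and Oasl2 17.3-fold (4.11 ± 0.11). In the other direction Ccn3 (-6.08 ± 0.11), Gstp1 (-5.30 ± 0.16), Eya1 (-5.00 ± 0.16), Ctsk (-4.58 ± 0.15) and Nedd4 (-4.54 ± 0.10) were the lowest. The limma test passed 1439 genes, 761 higher and 678 lower, and 294 and 190 of them differed at least 2-fold. The comparisons of the lines without and with beads share no arrays. Of the genes that passed, 606 were higher in both, where 28.8 are expected by chance, 584 were lower in both (30.3 expected) and 0 went opposite ways. The expected counts assume independent calls, but both comparisons use the same fit and the same estimate of each gene's spread. Across genes the differences correlated at r = 0.927, genes not being independent replicates.

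Others among the highest were Slc43a3 (3.99 ± 0.21), Il7r (3.69 ± 0.13), Ifit1 (3.60 ± 0.18), the cell fusion receptor Dcstamp (3.41 ± 0.18), Cxcl16 (3.39 ± 0.24), the antiviral Rsad2 (3.38 ± 0.14) and Clec2d (3.36 ± 0.19). The wild-type signal of Rtp4, Il7r and Ifit1 lay below the 25th percentile of all 3 bead arrays. Among the lowest were Mrc1 (-3.78 ± 0.20), Apoe (-3.58 ± 0.16), Il13ra1 (-3.37 ± 0.24), Tspan10 (-3.28 ± 0.17), Klk1b11 (-3.22 ± 0.14), Atp2a3 (-3.11 ± 0.18) and Maf (-3.06 ± 0.14). Tnf was higher by 0.69 ± 0.12 (adjusted p = 0.00814), and Clec7a differed by -0.65 ± 0.23 and did not pass (adjusted p = 0.165). Clec7a did pass without wild-type bead array 3 (-0.91, adjusted p = 8.98e-04), after quantile normalisation of the table (-0.63, 0.0325), with array weights (-0.99, 7.9e-05) and with the signal range covariate (-0.63, 1.64e-04). Its adjusted p ran from 7.9e-05 to 0.810 over the alternatives.

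Interferon-stimulated genes were again higher in 30 and lower in 0 of 35 (32 and 0 adjusted over the list alone), with a median of 1.85 and a camera adjusted p of 3.2e-57. MHC class I genes were higher in 7 of 14 (9 higher and 1 lower adjusted over the list alone; camera adjusted p = 1.8e-08) and NF-kappaB regulators in 12 of 23 (14 adjusted over the list alone; camera adjusted p = 6.2e-15). Immediate early genes were higher in 14 and lower in 1 of 32 (18 and 1 adjusted over the list alone; camera adjusted p = 3.1e-15), with Dusp1 (2.97 ± 0.15) and Klf6 (2.94 ± 0.13) first. Cell cycle genes were lower in 7 of 31 (16 adjusted over the list alone; median -0.41; camera adjusted p = 3.8e-12, but adjusted p = 0.531 with an estimated correlation). Mcm2 (-0.93 ± 0.09) and Ccne1 (-0.90 ± 0.13) again had the lowest values. Toll-like receptors were higher in 6 and lower in 2 of 33 (10 and 3 adjusted over the list alone; camera adjusted p = 0.00904, but adjusted p = 0.781 with an estimated correlation). That call also ended without wild-type bead array 3 (adjusted p = 0.606) and without knockout bead array 2 (0.157).

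The remaining lists did not pass camera with beads, and 6 of these differed in sign between median, mean and test: cytokines, eicosanoid genes, oxidative burst, macrophage identity, dendritic cell markers and sex-linked transcripts. The integrins Itga5 (1.62 ± 0.18) and Itgav (1.60 ± 0.12) and the plasminogen activator Plau (1.03 ± 0.14) were among 5 higher matrix and adhesion genes of 25, with 3 lower (5 and 3 adjusted over the list alone). Chemokines were higher in 5 and lower in 5 of 25 (7 and 5 adjusted over the list alone), with Cxcl14 at 2.67 ± 0.14, and eicosanoid genes higher in 3 and lower in 1 of 19 (3 and 2 adjusted over the list alone), with Ptgs2, the inducible cyclooxygenase, at 1.10 ± 0.20. Among NRF2 genes 3 were higher, Me1 (0.91 ± 0.19) and Taldo1 (0.75 ± 0.10) among them, and 2 lower of 20 (4 and 2 adjusted over the list alone).

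The count of 1439 was 693 and 597 without knockout bead array 1 or 2 and 4171 without wild-type bead array 3. It was 704 after centring on the median, 2263 after quantile normalisation of the table, 480 in a fit of the compared groups alone, 6083 with array weights and 4238 with the signal range covariate. Of 36 named genes that passed, Ccne1, Me1, Ptgs2, Taldo1 and Tnf lost their call after centring on the median and in a fit of the compared groups alone.

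In the wild-type line, 4 h with beads left no gene past the test. The largest group value belonged to cholesterol biosynthesis and efflux, where 19 of 21 genes had negative values (median -0.30), among them the synthesis enzymes Msmo1 (-0.63 ± 0.21), Hmgcs1 (-0.51 ± 0.11) and Idi1 (-0.51 ± 0.29) and the sterol sensor Insig1 (-0.51 ± 0.22). The list's median signal was 8.12, 8.21 and 8.22 in the bead arrays and 8.47, 8.53 and 8.45 in the unstimulated arrays. All 3 bead arrays thus lay below all 3 others. For a list singled out beforehand, chance gives such a separation, in either direction, in 10% of cases. This list was picked for its value among the 23 lists, so chance separates it more often than that. Without array 3 Msmo1 was at -0.35, Insig1 at -0.23 and Idi1 at -0.19, while Hmgcs1 was at -0.43. Tnf gave 0.24 ± 0.11, Clec7a 0.08 ± 0.21 and Tlr9 0.07 ± 0.14. Clec7a read 8.29, 8.49 and 7.61 in the bead arrays and 8.04, 8.12 and 7.99 in the others; without array 3 its change was 0.34 (adjusted p = 0.389) and without array 2 it was -0.10. Tlr9 turned to -0.04 without array 3 and was at 0.17 without array 1. The limma test passed 0 of 19938 genes, 167 had an unadjusted p under 0.05 where 997 are expected by chance, and the smallest adjusted p was 0.999999 (Id1), with 3 arrays in each group. With the signal range of each array as a covariate, added after the data were seen, 2 genes passed. With array weights 9174 did, in a fit that rested largely on 2 of the wild-type arrays. Among these were all 16 genes named for this response except Idi1 and Tlr9. Tnf was at 0.31 (adjusted p = 0.00103, over its alternatives 0.00103 to 0.999999) and Clec7a at 0.47 (adjusted p = 7.03e-04, over its alternatives 7.03e-04 to 0.999999).

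By camera, cholesterol genes were lower than other genes with an adjusted p of 1.5e-21 (adjusted p = 0.0796 with an estimated correlation); Hmgcs1 alone passed adjusted over the list alone, against 0 over all genes. Without wild-type bead array 3 the median was -0.18 and the camera adjusted p 9.5e-04. Glycolysis and hypoxia genes were lower with an adjusted p of 2.1e-08 (adjusted p = 0.0796 with an estimated correlation; 18 of 22 negative, median -0.12); Ndrg1 (-0.38 ± 0.10) and P4ha1 (-0.33 ± 0.08) passed adjusted over the list alone, and 0 over all genes. That list did not pass without wild-type bead array 3 (adjusted p = 0.0754). Matrix and adhesion genes, 22 of 25 positive (median 0.10, the macrophage elastase Mmp12 at 0.53 ± 0.14), had an adjusted p of 7.5e-04 (adjusted p = 0.321 with an estimated correlation), and adjusted p = 0.421 without array 3, where their median was -0.03.

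Results of camera for 3 further lists in the wild-type bead arrays rested on single arrays or on the scaling. Cell cycle genes were lower (median -0.10, adjusted p = 3.6e-04; adjusted p = 0.927 with an estimated correlation) but higher without array 3 (median 0.10, adjusted p = 0.0201), and did not pass without unstimulated array 2 (adjusted p = 0.400). Immediate early genes were higher (median 0.08, adjusted p = 0.0313; adjusted p = 0.501 with an estimated correlation), with Nr4a1 at 0.29 ± 0.10 and Jun at -0.32 ± 0.11 (-0.21 without unstimulated array 2), and did not pass without bead array 1, 2 or 3 or unstimulated array 2 (adjusted p = 0.304, 0.0607, 0.106 and 0.352). NRF2 genes were higher (median 0.02, adjusted p = 0.0156; adjusted p = 0.927 with an estimated correlation), with Srxn1 at 0.39 ± 0.20 and Gclm at 0.33 ± 0.12; their median turned negative (-0.00246) and the call ended (adjusted p = 0.131) after centring on the median. It also ended without bead array 1 or 2 or unstimulated array 1 or 3 (adjusted p = 0.878, 0.845, 0.0970 and 0.0823), while without array 3 the median was 0.16 with an adjusted p of 1.6e-06. The other 17 lists did not pass, and 0 of their members did in limma, over all genes or adjusted over the list alone. Without array 3, 8 of those 17 lists passed with the preset correlation. Among them were Dectin-1 signalling (median 0.14), Toll-like receptors (0.0754) and lysosome genes (0.0670). Lymphocyte (-0.10) and stromal markers (-0.15) passed too, and the test of each of these lists had the other direction with all arrays. With all arrays, 7 of the 17 differed in sign between median, mean and test: NF-kappaB, Dectin-1, Toll-like receptor, eicosanoid, MHC class II, dendritic cell and sex-linked genes.

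**Figure D4:**
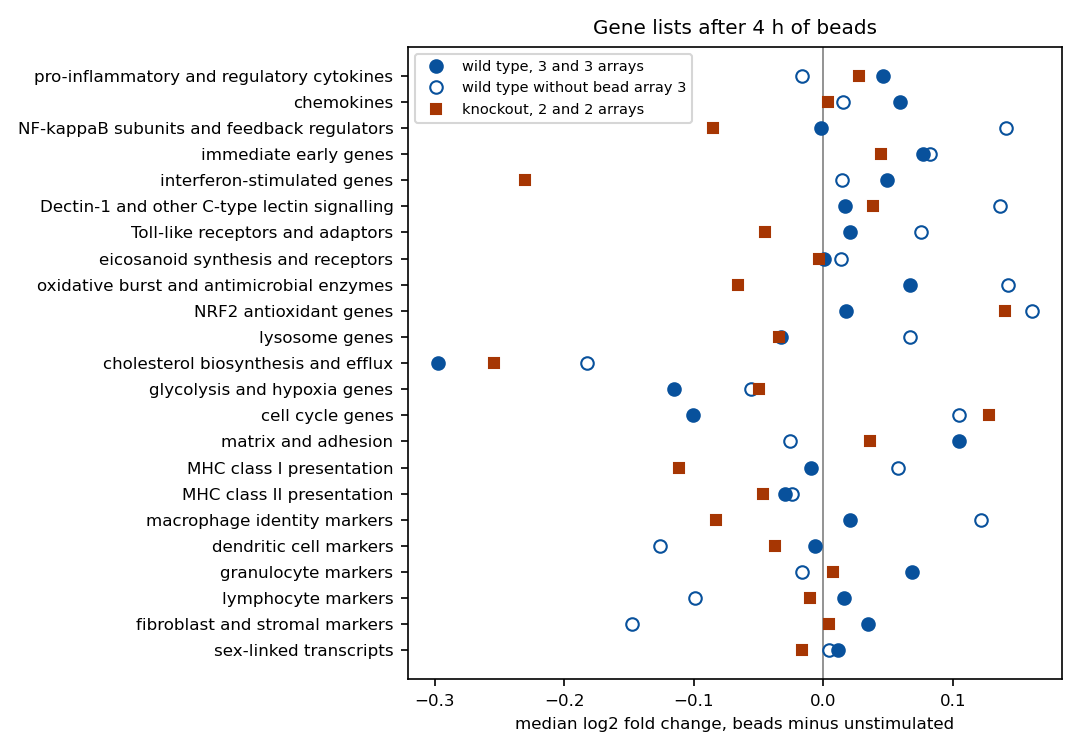
Median log2 difference, beads minus unstimulated (x axis), of the measured members of each of the 23 gene lists (y axis), in the wild-type line with all arrays (filled circles) and without bead array 3 (open circles), and in the knockout line (squares). Cholesterol genes lie at -0.30, -0.18 and -0.25.

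In the knockout line, with 2 arrays in each group, beads also left no gene past the test. The largest values in the lists were those of the endosomal RNA receptor Tlr8 (-1.03 ± 0.24), the transcription factor Maf (-0.86 ± 0.15), the integrin Itga5 (0.80 ± 0.19), Hpgd (-0.76 ± 0.20), the cystine transporter Slc7a11 (0.74 ± 0.28) and Dusp1 (0.71 ± 0.17). Tnf gave 0.10 ± 0.14, Clec7a -0.26 ± 0.25 and Tlr9 -0.20 ± 0.17. The limma test passed 0 genes, 359 had an unadjusted p under 0.05 (997 expected by chance), and the smallest adjusted p was 0.514, for the proteoglycan Sdc1. Without wild-type bead array 3, which is not part of the comparison, 17 genes passed, with array weights 16, and with the signal range covariate 110. Without bead array 1 the values of Hpgd, Dhx58 and Ddx58 were -0.48, -0.38 and -0.33, Clec7a was at -0.07 and Tnf at 0.23. Without bead array 2, Tnf was at -0.03, Clec7a at -0.46 and Myc at 0.45. Tlr9 was at -0.11 and Srxn1 at 0.39 without unstimulated array 2, and Irf1 was at -0.20 as the mean of its probe sets.

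Interferon-stimulated genes were lower than other genes after beads, 27 of 35 with negative values (median -0.23, camera adjusted p = 9.3e-13; adjusted p = 0.186 with an estimated correlation). The list's median signal was 8.32 and 8.38 in the bead arrays and 8.58 and 8.33 in the unstimulated arrays, so unstimulated array 2 lay between the bead arrays. Dhx58 (-0.64 ± 0.17), Trim30a (-0.61 ± 0.24), the RNA sensor Ddx58 (-0.59 ± 0.18) and Rtp4 (-0.57 ± 0.18) had the largest values, and 3 genes passed adjusted over the list alone, against 0 over all genes. These were Dhx58, Oasl2 (-0.51 ± 0.12) and Irf1 (-0.42 ± 0.10), the last 2 chosen after their values were seen. The list's median was -0.12 without bead array 1 (adjusted p = 0.0280) and -0.35 without bead array 2. Cholesterol genes were lower too, 17 of 21 negative (median -0.25, camera adjusted p = 2.0e-09; adjusted p = 0.296 with an estimated correlation), with Dhcr7 at -0.45 ± 0.16 and 0 passing adjusted over the list alone; the median was -0.12 without bead array 1 and -0.11 without unstimulated array 2, and Dhcr7 was at -0.28 without unstimulated array 1. NRF2 genes were higher, 17 of 20 positive (median 0.14, camera adjusted p = 2.3e-09; adjusted p = 0.447 with an estimated correlation). Srxn1 gave 0.68 ± 0.25, Gclm 0.50 ± 0.15 and the heme oxygenase Hmox1, the 1 gene that passed adjusted over the list alone, 0.52 ± 0.11. The list's median signal was 10.30 and 10.61 in the bead arrays and 10.37 and 10.13 in the unstimulated arrays, so unstimulated array 1 lay between the bead arrays. The median of NRF2 genes was 0.26 without bead array 1 and 0.27 without unstimulated array 1. Matrix and adhesion genes were higher (median 0.04, camera adjusted p = 3.4e-04; adjusted p = 0.296 with an estimated correlation), and 3 passed adjusted over the list alone, Itga5, the urokinase receptor Plaur (0.69 ± 0.14) and Itgav (0.68 ± 0.13). The median of this list turned to -0.03 without bead array 1 and -0.02 without unstimulated array 1, where the call held.

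Cell cycle genes were higher in the knockout line, 27 of 31 positive (median 0.13, camera adjusted p = 5.1e-06; adjusted p = 0.618 with an estimated correlation). The list's median signal was 8.90 and 9.24 in the bead arrays and 9.04 and 8.92 in the others, and the call ended without bead array 2 (median 0.07, adjusted p = 0.150) or unstimulated array 2 (adjusted p = 0.0604). Macrophage identity markers were lower (median -0.08, camera adjusted p = 8.2e-05; adjusted p = 0.447 with an estimated correlation), and Maf passed adjusted over the list alone; without bead array 1 the list did not pass (adjusted p = 0.0648). Toll-like receptors were lower (camera adjusted p = 0.00787; adjusted p = 0.618 with an estimated correlation), Tlr7 at -0.64 ± 0.29 beside Tlr8, as was MHC class I presentation (median -0.11, camera adjusted p = 0.0192; adjusted p = 0.464 with an estimated correlation). Both calls ended without bead array 1 (adjusted p = 0.907 for each), where the medians turned positive, and without unstimulated array 1 (adjusted p = 0.317 and 0.151). Immediate early genes did not pass camera (adjusted p = 0.182), but 3 passed adjusted over the list alone, Dusp1, Myc (0.69 ± 0.15) and Fosl1 (0.66 ± 0.14). The mixed fry test passed for this list (adjusted p = 0.0422) and for interferon-stimulated genes (0.00535). Adjusted over the list alone, 1 gene passed in each of cytokines (the interleukin 1 antagonist Il1rn, 0.60 ± 0.11), chemokines (Cxcl14, 0.69 ± 0.16), lymphocyte markers (Il7r, 0.68 ± 0.14) and glycolysis and hypoxia (Ndrg1, -0.54 ± 0.12). Median, mean and test differed in sign for 5 lists that did not pass, those of Dectin-1 signalling, granulocytes, lymphocytes, stroma and sex-linked transcripts.

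The difference between the bead responses of the lines asks what the series was made for, whether the response changes without TLR9. Interferon-stimulated genes had a more negative response in the knockout line, 29 of 35 with negative differences (median -0.24, camera adjusted p = 2.6e-12; adjusted p = 0.202 with an estimated correlation), among them Trim30a (-0.75 ± 0.31), Dhx58 (-0.74 ± 0.22), the RNA sensor Ifih1 (-0.70 ± 0.21) and Oasl2 (-0.63 ± 0.15). The lines started from unlike levels of this list. Its median signal was 6.29, 6.24 and 6.25 in the unstimulated wild-type arrays and 8.58 and 8.33 in the unstimulated knockout arrays. Whether the starting level accounts for the difference between the responses was not tested. Single genes with large values in other lists were Tlr8 (-1.04 ± 0.31), Hpgd (-0.95 ± 0.25), Maf (-0.77 ± 0.19), Dusp1 (0.76 ± 0.22) and Ebi3 (-0.71 ± 0.33). The difference was -0.13 ± 0.17 for Tnf, -0.35 ± 0.33 for Clec7a and -0.27 ± 0.22 for Tlr9. Ebi3 was at -0.30 without unstimulated knockout array 1 and -1.12 without array 2, Dhx58 at -0.48 without knockout bead array 1, and Clec7a at -0.15 without that array and -0.61 without wild-type bead array 3. Over the alternatives Tnf ran from -0.26 to -7.92e-04 and Tlr9 from -0.37 to -0.14, with Tnf highest without knockout bead array 1 and Tlr9 highest without unstimulated wild-type array 2. The limma test passed 0 genes, 172 had an unadjusted p under 0.05 (997 expected by chance), and the smallest adjusted p was 0.99997. Without wild-type bead array 3, 1 gene passed, Cd72, a gene chosen after its values were seen (-1.09 ± 0.11, adjusted p = 0.0381, over its alternatives 0.0381 to 0.999997). With array weights 9 genes passed, and with the signal range covariate 2.

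By camera, 4 further lists differed between the responses. Cell cycle genes had 30 of 31 positive differences (median 0.24, adjusted p = 3.3e-10; adjusted p = 0.821 with an estimated correlation), but a median of 0.08 and an adjusted p of 0.364 without wild-type bead array 3, and a median of 0.12 without knockout bead or unstimulated array 2. Macrophage identity markers had 21 of 25 negative differences (median -0.08, adjusted p = 3.4e-04; adjusted p = 0.821 with an estimated correlation), with the complement gene C1qa at -0.53 ± 0.17 beside Maf; their median was -0.26 without array 3, and the call ended without wild-type bead array 1 or 2 (adjusted p = 0.104 and 0.122). NRF2 genes (median 0.07, adjusted p = 0.00184; adjusted p = 0.848 with an estimated correlation) did not pass without array 3, where the median was -0.01, or without knockout bead or unstimulated array 2 (adjusted p = 0.385 and 0.256). Oxidative burst genes had 12 of 15 negative differences (median -0.08, adjusted p = 0.0367; adjusted p = 0.821 with an estimated correlation), with Acod1, the itaconate-producing enzyme, at -0.55 ± 0.18; their median was -0.14 without array 3, and the call ended when any of 6 other arrays was left out (adjusted p = 0.0615 to 0.487). No member of any list passed adjusted over the list alone, and median, mean and test differed in sign for immediate early, Dectin-1, matrix, lymphocyte and sex-linked genes, none of which passed. Across genes, the bead responses of the lines correlated at r = 0.124, and 0.168 without array 3, genes not being independent replicates.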

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

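Of the tests in this part, the split count of the wild-type arrays was planned; the tests on wild-type bead array 3, on the signal range of the arrays, on other cell types and on Tlr9 itself were chosen only after the result was seen.

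The bead responses of the lines differed, by camera on the difference itself, in 5 gene lists: interferon-stimulated genes (median -0.24), oxidative burst genes (-0.0807), NRF2 antioxidant genes (0.0686), cell cycle genes (0.24) and macrophage identity markers (-0.0835). All 5 calls were lost with an estimated correlation (adjusted p = 0.202, 0.821, 0.848, 0.821 and 0.821 with an estimated correlation), and those of NRF2 and cell cycle genes also ended without wild-type bead array 3. For interferon-stimulated genes the lines also started from unlike levels, and whether this accounts for the difference was not tested. Outside the gene tests, 179 of 7064 probe sets that were shared by several genes or not named differed between the unstimulated lines, 102 higher and 77 lower in the knockout line, and 151 did with beads. Groups of 2 and 3 arrays are too small to test single arrays against their group.

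Wild-type bead array 3 stood apart from all other arrays, and its displacement on the first component lay 40.4% of the way to the knockout arrays. A share of knockout RNA that large would raise the 24 genes that are at least 8 times higher in the knockout line by a median of 2.24 on the log2 scale, but their median change in this array was 0.186, which argues against such a mixture. A bead effect in that culture alone would be unrelated to arrays that saw no beads. The array's deviation correlated across genes with the difference between the unstimulated knockout arrays (r = 0.561, and 0.521 after removing the signal level). The signal level explained 43.6% of the variance of its deviation, too little to settle whether a compressed signal range accounts for the pattern. The deviation correlated with the difference between the knockout bead arrays at r = 0.773. Both knockout pairs were ordered from narrower to wider signal range, and pairs ordered so tend to a positive r. Between the knockout pairs themselves r was 0.591, and 0.543 after removing the signal level. The correlations with either pair therefore do not decide whether beads acted in that culture alone.

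No gene passed for the bead response of either line. In the knockout line, 110 genes passed with the signal range of the arrays as a covariate, and 100 of 100 random covariates passed fewer (highest 22). The signal range may thus have added to the spread. It was computed from the same values, unlike the random covariates, so this comparison does not show that the signal range hid a bead response. In the wild-type line the same covariate lowered the median SE from 0.129 to 0.0730, but only 2 genes passed, Skil and Msmo1, which were chosen after their values were seen. There too 100 of 100 random covariates passed fewer (highest 0). With so few genes passing, how far the signal range accounts for the count of 0 in the wild-type line stays open. Whether it accounts for the shortfall of small p stays open: 1321 genes had an unadjusted p under 0.05 with it, against 167 without (997 expected by chance), and 94 of 100 random covariates gave fewer (highest 6980). All 10 splits of the 6 wild-type arrays passed as many genes (0 in the real split, and 0 as the highest of the others), and 10 splits are too few for a share under 0.05. By unadjusted p under 0.05, the split with wild-type bead arrays 1 and 2 and unstimulated array 2 on 1 side gave 7442 genes against 167 in the real split, which points to a structure of the samples; those 3 arrays had the 3 widest signal ranges of the 6.

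Interferon-stimulated genes were higher in the knockout line with and without beads. Their median was 2.27 with the signal range as a covariate, against 2.26 without. The signal ranges of the unstimulated lines overlapped, at 1.90 to 1.96 in wild type and 1.87 to 1.91 in knockout. The covariate could therefore shift this median little, and the unchanged median decides nothing about the signal range. Unstimulated wild-type array 3 and knockout array 1, with signal ranges of 1.90 and 1.91, had list medians of 6.25 and 8.58. Of 58 measured markers of dendritic cells, granulocytes, lymphocytes and stroma outside the interferon list, 1.72% (1 gene, Il7r) were higher, which argues against other cell types in the knockout cultures; the median marker signal there was 5.25, against 6.12 for all genes. The loss of Tlr9 itself and another difference between the lines cannot be told apart: Tlr9 signal was higher by 0.367, which did not pass, the place of its probe set is unknown, and line and genotype divide the arrays in the same way.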

How the results depend on the processing

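The signal range covariate, the list tests with an array left out and the list tests under other scalings were chosen only after the result was seen.

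The counts of the lines without and with beads were 756 (415 higher, 341 lower) and 704 (417 and 287) after centring on the median, 2483 and 2263 after quantile normalisation of the table, 3262 and 480 in fits of the compared groups alone, 505 and 484 at a change of at least 2-fold, and 4451 and 6083 with array weights. Array weights gave 9174 genes for the wild-type bead response, 16 for the knockout response and 9 for their difference; the weights were 12.1 for wild-type bead array 2, 5.27 for unstimulated wild-type array 3 and 0.0701 for wild-type bead array 3, so that the wild-type comparison rested largely on 2 arrays. With the signal range covariate the counts were 2, 110, 2, 4297 and 4238, in the order wild-type response, knockout response, difference, lines without beads, lines with beads. Leaving out each array in turn gave 0 to 17 for the knockout response and 0 to 1 for the difference, both highest without wild-type bead array 3, 681 to 3668 for the lines without beads and 597 to 4171 with beads; the wild-type response stayed at 0. The lowest of these left 1 array in a group, assumed to vary like the other groups. All 1645 and 1439 genes kept their call and direction with the covariate, without wild-type bead array 3 and with array weights. These settings all raised the counts, so that the calls would be kept was likely beforehand. The overlap was not counted for settings that lowered the counts, such as centring on the median. Trended or robust eBayes, centring on the 75th percentile, the filters on signal and the mean over probe sets kept each count within 1.5 times. Tlr9 ranged from 0.24 to 0.46 over the alternatives.

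Without wild-type bead array 3, the camera test changed direction in 8 lists: in the wild-type response Dectin-1 signalling (0.14; lowest with another array left out -0.0754), Toll-like receptors (0.0754; -0.0411), lysosome (0.0670; -0.0814), cell cycle (0.10; -0.14), lymphocyte markers (-0.10; highest 0.0753) and stromal markers (-0.15; 0.18), and in the difference NRF2 (-0.0147; 0.17) and lysosome genes (-0.0846; 0.0431). The median, not the test, turned for matrix genes in the wild-type response (-0.03). Another 10 list calls were gained and 6 lost. Leaving out each of the other 9 arrays gained 31 list calls, ended 28 and turned the test of MHC class I in the knockout response (0.00234 without bead array 1; -0.19 without bead array 2). Among lists that passed, the median but not the test turned for Toll-like receptors (0.0212) and matrix genes (-0.0313) in the knockout response without bead array 1, for matrix genes without unstimulated array 1 (-0.0242), and for NRF2 genes in the wild-type response without bead array 1 (-0.0288) or 2 (-0.00324). An estimated correlation ended 25 list calls. The fry test ended 21 and added 2, the covariate ended 3 and added 5, centring on the median ended 4, centring on the 75th percentile ended 2 and added 2, quantile normalisation ended 2 and added 4, and the filter above 5 added 2. No scaling moved the median of all genes by more than 0.0525. Beyond fewer arrays or a stricter threshold, the cause was not tested. Detection calls or signal over background were not available, so what low signal limits stays unknown.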

Other observations

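Of the tests in this part, the one on genes near Tlr9 was planned, with its interval added after its value was known; the signal range covariate and the test of a shared bead response were chosen only after the result was seen.

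With the signal range of each array as a covariate, 57 genes rose and 53 fell after beads in the knockout line. Without the covariate 0 genes passed, so none of the changes named here passed in the main fit. The widest gap in signal range within a group was that of wild-type bead array 3 (1.75 against 2.00 and 1.98). The covariate's slope therefore rests largely on an array outside this comparison. With that array left out instead, 17 genes passed. The genes named here were chosen after their values were seen. Leaving out predicted genes, rises were led by Olfml3 (1.41 ± 0.20), the Notch ligand Jag1 (0.97 ± 0.13), the ectonucleotidase Nt5e (0.91 ± 0.11), the transcriptional repressor Id2 (0.87 ± 0.09) and the transglutaminase Tgm2 (0.83 ± 0.08). Others that rose were Itga5 (0.76 ± 0.10), Itgav (0.66 ± 0.10), the urokinase receptor Plaur (0.67 ± 0.09) and Sdc1 (0.71 ± 0.08), the protease Furin (0.76 ± 0.08), and Dusp1 (0.68 ± 0.08), Myc (0.68 ± 0.12), Ptgs2 (0.60 ± 0.10) and Il1rn (0.58 ± 0.08). Falls were led by the phosphodiesterase Pde7b (-1.21 ± 0.18), the endosomal receptor Tlr8 (-1.08 ± 0.10), Ms4a6b (-0.90 ± 0.17), Sesn1 (-0.86 ± 0.09), Cyria (-0.86 ± 0.08), Maf (-0.86 ± 0.13) and Gpr162 (-0.80 ± 0.09). Cd28 (-0.71 ± 0.09) and the endosomal receptor Tlr7 (-0.71 ± 0.09) fell too. In the fit without the covariate, Ms4a6b was at -0.50 without knockout bead array 1. Among the interferon-stimulated genes, Trim30a (-0.66 ± 0.09), Ddx58 (-0.62 ± 0.12) and Oasl2 (-0.51 ± 0.10) fell. In limma with the covariate the adjusted p was 0.00749 for Trim30a and 0.0499 for Ddx58, and without it 0.999992 for both. For Oasl2 the lowest adjusted p over the alternatives was 0.0499.

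In the wild-type line, the same covariate passed Skil, a repressor of SMAD signalling, which rose (0.83 ± 0.06, adjusted p = 7.7e-04), and the cholesterol synthesis enzyme Msmo1, which fell (-0.58 ± 0.06, adjusted p = 0.00539). The difference between the responses passed for Tlr8 (-1.14 ± 0.13) and Tgm2 (0.81 ± 0.10), each with an adjusted p of 0.0345. These 4 results were chosen after their values were seen. Over all alternatives the adjusted p ran from 2.7e-05 to 0.999999 for Skil, from 0.00281 to 0.999999 for Msmo1, and from 0.0345 to 0.999997 for Tlr8 and for Tgm2.

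A hypothesis was that the lines share a bead response. Of the 57 genes that rose in the knockout line with the covariate, 51 had positive values in the wild-type line (median 0.12), and of the 53 that fell, 34 had negative values (median -0.08). In the wild-type arrays without the covariate, the medians of these sets differed by 0.225 in the real split and by at most 0.212 in the other 9 splits; 10 splits are too few for a share under 0.05.

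Knockout lines made in cells of another strain may carry DNA of that strain around the target gene. Of 181 tested genes within 5 Mb of Tlr9 (gene order from the GRCm38.p6 annotation), 19 differed between the unstimulated lines, 4 higher and 15 lower in the knockout line, a share of 10.5% (6.44% to 15.9%, exact 95% interval) against 8.27% elsewhere. That share was at percentile 85.8 among 190 windows with as many neighbouring genes elsewhere, whose 95th percentile was 13.8%; within 10 Mb it was 9.16%, at percentile 75.2. The share lay below the 95th percentile, but its interval reaches above it, so this stays open. The interval treats neighbouring genes as independent, and the windows overlapped one another. Over all genes, 890 of the 1645 that passed were lower in the knockout line. Whether the direction of the genes near Tlr9 differs from that was not tested.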
